A study of Mus musculus with 12 samples.

How the data were processed

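The 12 sequencing libraries were prepared from mouse striatal RNA with the Lexogen SENSE mRNA-Seq kit, per the labels' protocols. The submitters' processing notes name Bowtie2 2.3.4.2, HTSeq and DESeq2, and give the genome build under the names GRCm38 and mm10. The role, order and settings of these tools are not given in the sources used here.

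One table of the whole series was examined. The names of its 12 value columns were compared with the title, description, source name and characteristics of each library, ignoring case, spaces and punctuation. No column matched a library, so all 12 columns were left unused and their unit was not relied on. The depth of each library is therefore not reported. Of the 23337 gene rows, 16 have a bare number in place of a gene symbol.

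Before the data were examined, 3 pairwise comparisons, 35 gene lists given by name and 48 processing alternatives were fixed. A ribosomal protein list, defined by a symbol pattern, and a rule for choosing named genes were fixed too. None of these was run, because each needs the treatment of every column. The same holds for the planned measures of overlap between comparisons and of return towards control. A planned check of sex-linked genes in each library does not need the treatments. It was not run either. The missing key did not prevent a check per column, but only the column names and gene names were used. The rule would have named the genes with the largest changes and the smallest p-values in each comparison, and the leading members of each list. It would also have named a fixed set: thyroid hormone related genes and Pvalb, Mbp and Ppp1r1b, which the plan lists as cell type markers. The labels also differ from the series design text on whether every mouse received PTU, and the grouping followed the labels of the individual libraries.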

Results

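RNA sequencing libraries were made from the striatum of mice at postnatal day 25. The labels place the 12 libraries in 3 groups of 4. The first group is labelled as euthyroid controls, although the series design text differs from the labels on whether every mouse received PTU. The second holds mice given PTU, taken here as propylthiouracil, a blocker of thyroid hormone synthesis, and labelled as hypothyroid. The third holds mice given PTU and thyroid hormone, labelled as rescued, with hormone treatment of 2 days per the series title.

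This design implies 3 pairwise comparisons. PTU against control asks which striatal transcripts differ in hypothyroid animals. PTU with thyroid hormone against PTU asks which transcripts respond to the hormone. PTU with thyroid hormone against control asks what still differs after treatment.

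None of these comparisons was made. The deposited table holds 23337 gene rows and 12 columns of values, and the columns carry serial names only. No such name occurs in the title, description, source name or characteristics of any library. As a result, 0 of the 12 columns were matched to a library, and the treatment behind each column is unknown here. All 12 columns were therefore left unused, and no expression level, fold change, library total or test is reported. Assigning treatments by the order of the columns would have been a guess, and assigning them from thyroid hormone responsive genes would have fixed the outcome in advance.

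The absence of reported changes carries no information about whether PTU or thyroid hormone altered gene expression in these animals.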

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

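The match of columns to libraries was repeated with other rules, chosen after the column names were seen. Searching every field of each library, protocols included, matched 0 columns to a single library. Comparing only the trailing number of the column name with that of the title also matched 0 columns to a single library: 4 columns shared their number with 3 libraries each, one from each group, and 8 columns shared it with none. The 48 processing alternatives fixed before the data were examined were not run. No paired analysis was possible because no column was tied to a library or to its replicate number.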
